A study of Mus musculus with 4 samples.

How the data were processed

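RNA from the dentate gyrus of the hippocampus of young male C57BL/6J mice was measured on oligonucleotide arrays, with 1 intensity per probe set and sample. The 4 samples came from mice that were handled and given no other treatment. RNA was taken 1, 2, 4 or 6 h after the last shock given to a parallel group of experimental mice, with 1 sample at each time. The samples of the shocked mice were not analysed here. The number of mice behind each sample, the time of day and the meaning of the word "1st" in the sample titles are not given in the sources used here.

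The deposited table holds 1 array intensity per probe set and sample on a linear scale, for 12488 probe sets. No label states how the authors made these values, and the scanner, the software and the scaling are not given in the sources used here. The mean intensity after leaving out the top and bottom 2% of probes was 500.3 on each of the 4 arrays, so a common scaling of whole arrays was inferred from the values. The quantiles differed between arrays, so the values had not been quantile-normalised. Because the trimmed means lay within 10% of each other, the values were used as deposited. The number of arrays limits the precision: each hour has 1 array, so no value at a single hour has a replicate error. The tests take their error from the scatter of the arrays about a fitted line and, through limma, from the other genes.

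Of the probe sets, 66 were array controls, 1193 had no gene symbol and 396 carried several symbols, and all of these were left out of the gene-level comparisons. The remaining 10833 probe sets named 8251 genes, and 10817 of them matched a mouse gene by identifier in a RefSeq gene table of assembly GRCm38.p6. That table was used for names and gene lengths, and none of its coordinates are given, since no genome build is named for the array. For the 2073 genes with more than 1 probe set, the probe set with the highest mean log2 intensity was used. Intensities under the 20th percentile of all values (38.3) were set to it, and log2 was taken. A gene was tested if its mean log2 intensity over the 4 samples was at or above the 40th percentile of the gene means (7.41, an intensity of 170.4). This left 4951 genes, of which 2 had any value at the floor (Trh at 1 h and Mrpl11 at 6 h). A ratio that involves such a value is given as a lower bound.

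A linear trend of log2 intensity on the hour of extraction was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 2 residual degrees of freedom and a median of 10.4 prior degrees of freedom. Benjamini-Hochberg adjusted p values over the 4951 genes were called at 0.05. These p values measure the scatter between samples around a line over 4 hours, in which the hour and the individual array cannot be separated. Gene lists were tested for a shared slope with limma's camera, two-sided, at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, adjusted over the 21 lists with at least 5 measured members. To describe single arrays, the median over a list of each gene's log2 at an hour minus its mean at the other 3 hours was set against 10000 random lists of the same size, matched on mean expression decile. A median outside the central 95% of those lists is a description of 1 array and carries no test between samples. A difference of over 2-fold between any hours was counted without a test. Pairs of arrays were compared by correlation across genes, which are not independent replicates.

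The lists, the tests, the filters, the alternatives and the rule for naming genes were fixed before the data were examined, apart from additions named as later choices. The lists cover immediate early genes, glucocorticoid response genes, circadian clock genes, the NF-kB pathway, heat shock and chaperones, glutamate receptors, GABA receptors, plasticity kinases and phosphatases, presynaptic vesicle genes, ribosomal protein genes, oxidative phosphorylation genes and proteasome genes. Others hold markers of dentate granule cells, CA field pyramidal and mossy cells, interneurons, astrocytes, oligodendrocytes, microglia, endothelial and mural cells, choroid plexus, thalamus and habenula, blood cells, and neurogenesis and immature neurons. Named genes are up to 10 per direction with a called trend. Where fewer than 5 were called in a direction, they are the 8 genes with the largest difference between 6 h and 1 h among those whose values move in 1 direction at every step. Also named are the 3 genes furthest above and the 3 furthest below the other hours at each hour, the 2 members of each list with the largest range, the 4 members of a called list with the largest slope in its direction, and the 2 members of each cell type list with the highest mean. Genes named outside this rule, as members of a list under discussion, were chosen after their values were seen.

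The trend test was tested on simulated data with the scatter of these arrays, over 10 simulations of 4951 genes of which 200 were given a slope. It recovered 23.5% of genes with a slope of 0.2 log2 per h and 85.6% of those with 0.4, and 6.1% of the calls were false. For the list test, 20 simulations of 21 lists with no change gave 3 calls in all, and a list planted with a slope of 0.1 was called in 100% of simulations. In simulations added after the results were seen, that list was called with an estimated correlation in 0% at a slope of 0.1 and 15% at 0.4, and by fry in 5% and 85%, so a miss in these settings says little about a small slope. These simulations draw genes independently of each other, which real genes are not, and take their scatter from the fit to these 4 arrays. That scatter is limma's moderated variance, and the 200 planted genes ease the adjusted cut-off. The shares recovered therefore need not hold for these data. In these data the gene Ada, with a slope of −0.66 log2 per h, had a limma adjusted p of 0.99993. The alternatives were quantile normalisation, scaling by the array median, 3 other treatments of low values, no filter or a filter at the 60th percentile, the mean of all probe sets of a gene, 3 other codings of the hour, 2 other variance settings, 2 other list tests, and leaving out each sample in turn. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.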

Results

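Gene expression was measured in the dentate gyrus, the hippocampal subfield of granule cells, from 4 samples of handled control mice taken at 1, 2, 4 and 6 h. The hours are those of a parallel experiment in which other mice received shocks, so the samples form a time series of unshocked controls with 1 array per hour. The question the design poses is how far expression in handled controls differs between the hours. Values are array intensities, given in the order 1, 2, 4 and 6 h, and a value at 1 hour comes from 1 array with no replicate. The median intensity of all probes was 185.6, 187, 213 and 184.8.

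Several bright markers of neurons and glia differed little between the 4 samples. Neurochondrin (Ncdn), a neuronal protein of dendrites, had a mean intensity of 34600 ± 2310 (SD, n = 4). The mean was 2630 ± 265 for calbindin 1 (Calb1), a calcium-binding protein of mature granule cells, and 10600 ± 684 for the neuropeptide cholecystokinin (Cck). Among glial genes the mean was 29700 ± 2460 for cystatin C (Cst3) of astrocytes, 4310 ± 134 for Bin1 of oligodendrocytes and 2510 ± 305 for cathepsin S (Ctss) of microglia. In log2 units the SD over the 4 samples was 0.1 for Ncdn, 0.14 for Calb1, 0.09 for Cck, 0.12 for Cst3, 0.05 for Bin1 and 0.18 for Ctss. Second probe sets read 828, 517, 617 and 749 for Bin1 and 1258, 1609.7, 1356 and 1789 for Cst3. Other bright markers spread more widely, with 0.37 for Bok of the CA field list, 0.4 for the vascular gene Cldn5 and 0.52 for the growth factor gene Igf2 of the choroid plexus list.

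Of the marker lists, 10 of 14 granule cell genes with a probe were past the filter, as were 10 of 15 CA field pyramidal and mossy cell genes, 10 of 17 interneuron genes, 17 of 18 astrocyte genes, 13 of 16 oligodendrocyte genes and 12 of 19 microglia genes. The same held for 10 of 20 endothelial and mural cell genes, 5 of 14 choroid plexus genes, 6 of 9 thalamus and habenula genes, 2 of 7 blood cell genes and 12 of 17 neurogenesis and immature neuron genes. Means over the 4 samples were 3480 ± 411 for Rgs14 and 1670 ± 402 for Bok of the CA field list, 3810 ± 253 for the GABA-synthesising enzyme Gad1, 23600 ± 2800 for the metallothionein Mt3, 5740 ± 544 for the myelin gene Mobp and 1530 ± 264 for the complement gene C1qc (SD, n = 4). Vascular genes had means of 918 ± 94.7 for Eng and 565 ± 147 for Cldn5. In the thalamus and habenula list the means were 1050 ± 180 for Calb2 and 585 ± 137 for Prkcd, and in the neurogenesis list 7810 ± 777 for Tubb3 and 3920 ± 429 for Ncam1 (SD, n = 4). A second Prkcd probe set, at 413, 486, 587 and 491, ran opposite to the one used. Over all lists, 351 of 485 different members with a probe were past the filter.

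Among genes whose values moved 1 way at every step, the widest differences between 1 h and 6 h were towards lower values. Adenosine deaminase (Ada), which breaks down adenosine, had intensities of 614.5, 336.5, 322.5 and 48.7, a 12.6-fold span that ends near the floor of 38.3. At 6 h it was −3.06 log2 from the other hours, or −2.47 with a floor at the 30th percentile and −2.36 with an added constant. The slope was −0.66 ± 0.13 log2 per h (SE, n = 4), but −0.27 without the 6 h sample and −0.1 with the mean of all probe sets. The mitochondrial ribosomal protein gene Mrpl11 read 349, 338, 194 and 37.5, at least 9.1-fold from 1 to 6 h. Nubp1, an iron-sulfur cluster assembly factor, read 363, 346, 303 and 52.7, and Bhmt, an enzyme of homocysteine metabolism, read 352, 325, 118 and 67.8. With values higher at each step, gluconokinase (Idnk) read 115, 311, 355.5 and 376, the clock output factor Dbp 333, 342, 611 and 761, and B2m, the light chain of MHC class I, 778.5, 1215, 1442 and 1731.

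None of these genes, and no other, passed the trend test. With limma, 0 of 4951 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.99993. At an unadjusted p under 0.05 there were 100 genes, 54 with a positive and 46 with a negative slope, where chance alone would give 248. Values moved up at every step in 131 genes and down at every step in 119, against 206 each way for arrays in random order. The other named genes with higher values at each step were Tcf25, Anln, Stxbp2, Reep6 and Galt, between 2.21-fold and 2.97-fold higher at 6 h than at 1 h. Those with lower values at each step were the adhesion gene Nectin2, the RNA-binding protein gene Khdrbs1, the splicing factor kinase Srpk1 and the unfolded protein sensor Atf6, between 2.42-fold and 4.73-fold higher at 1 h than at 6 h. Of the other Ada probe sets, one lay under the floor at every hour and shows no course (11, 20.8, 20 and 30), and the other was above the floor at 6 h alone (34.4, 17.5, 13.2 and 139.8). A second Nectin2 probe set read 187, 156, 331 and 124. That of Bhmt lay under the floor at every hour (9.1, 9.3, 18.4 and 16.2). Second probe sets of Stxbp2 (205, 109.9, 451.5 and 238), Galt (30.8, 103, 129.7 and 28.9) and Tcf25 (143, 234.5, 218 and 295) were not higher at each step. Leaving out the 1 h sample gave 13 called genes and leaving out the 6 h sample gave 3, each from a line through 3 arrays with 1 residual degree of freedom.

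Circadian clock genes were the 1 list of 21 called for a shared slope with the hour, and the slope was upward (camera adjusted p = 0.02, 10 of 14 genes with a positive slope). With an estimated correlation between genes limma's camera gave an adjusted p of 0.84, in a setting that called a planted slope of 0.1 in 0% of simulations. Dbp, a transcription factor whose RNA cycles strongly under clock control, had a slope of 0.26 ± 0.08 log2 per h and was 2.29-fold higher at 6 h than at 1 h. Nr1d2, which encodes the nuclear repressor REV-ERB beta, read 373, 393, 480.2 and 671, with a slope of 0.17 ± 0.07. Cry2, a repressor of the core clock activator, read 220, 124, 386 and 285 (slope 0.18 ± 0.13), and Timeless read 242, 320, 484 and 378 (slope 0.14 ± 0.09; SE, n = 4 throughout). Without the 6 h sample the slopes of Cry2 and Timeless were 0.35 and 0.33. The values of Per3 were 224.5, 262, 255 and 319.9, those of Per1 357, 358, 299 and 564 and those of Arntl, the core activator BMAL1, 618, 414, 316 and 584.

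The median slope of the 14 clock genes was 0.05 log2 per h. The list was not called by fry (adjusted p = 0.43), which called a planted slope of 0.1 in 5% of simulations. Over the alternatives with all 4 samples, the list's adjusted p ran from 0.016 with array median scaling to 0.84 with an estimated correlation. With an estimated correlation and the 2 h sample left out, camera gave the list an adjusted p of 0.95. No member passed when adjusted over the list alone (smallest adjusted p = 0.0577), and 0 passed over all genes. The call was lost without the 1 h sample (adjusted p = 0.08) and without the 6 h sample (adjusted p = 0.5). In a count added later, the hours were placed in each of their 24 orders over the same arrays. At least 1 list was called in 15 orders. In 12 orders some list had a camera p as small as that of the clock list in the real order.

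**Figure D1:**
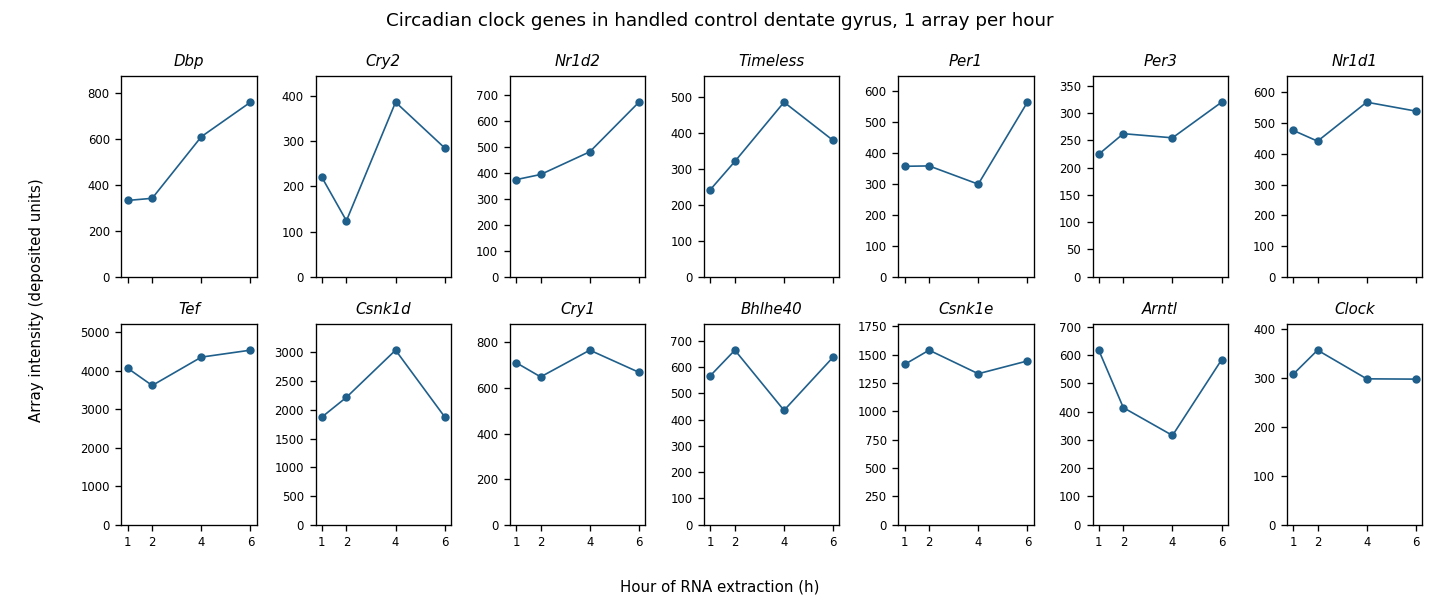
Array intensity of the 14 tested circadian clock genes (vertical axes, linear from 0 with a separate scale for each gene) against the hour of RNA extraction; each point is 1 array of handled control dentate gyrus. Genes are ordered by slope from Dbp, at 0.26 log2 per h, to Clock, at −0.03, and 10 of the 14 slopes are positive.

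The other 20 tested lists were not called, with camera adjusted p values from 0.37 to 0.98 and, with an estimated correlation, from 0.84 to 0.99. Stress-related lists had slopes in both directions: 11 of 21 immediate early genes had positive slopes (adjusted p = 0.92), as did 11 of 19 glucocorticoid response genes (adjusted p = 0.65), 5 of 9 NF-kB pathway genes (adjusted p = 0.54) and 6 of 17 heat shock and chaperone genes (adjusted p = 0.4). Fos, an activity-induced transcription factor, read 180.2, 250.4, 119 and 161, Egr1 546, 1349, 861 and 817, Junb 379, 222, 94.5 and 379 and Ier2 209.5, 240.5, 224 and 93.9. A second Junb probe set, with a mean under the filter, read 98, 55.4, 44.2 and 48.2. The glucocorticoid-induced gene Fkbp5 read 1162, 1044, 1415 and 1020, Sgk1 906, 786, 612 and 1270.5, Ddit4 1062, 493, 978.5 and 1205 and the cell cycle inhibitor Cdkn1a 273, 296.5, 83.7 and 318, while a second Cdkn1a probe set read 171, 236, 185.5 and 178. The NF-kB subunit Relb read 209, 257.5, 449 and 179.7, the receptor Tnfrsf1a 92.8, 174, 354 and 175, and the chaperones Hspd1 and Stip1 6077, 5509, 3054 and 5997 and 259, 182, 379 and 137. A second Tnfrsf1a probe set was highest at 6 h, with 91.8, 135, 159 and 270.

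For neuronal and glial lists, positive slopes were counted in 3 of 6 glutamate receptors (adjusted p = 0.94), 9 of 22 plasticity kinases and phosphatases (0.37), 6 of 17 presynaptic vesicle genes (0.92), 5 of 10 granule cell markers (0.94), 3 of 10 CA field markers (0.94) and 5 of 10 interneuron markers (0.54). The CA field list had a median slope of −0.02 and a mean slope of 0.01, and camera gave its direction as down. The counts were 10 of 17 for astrocyte markers (adjusted p = 0.69), 7 of 13 for oligodendrocyte markers (0.98), 6 of 12 for microglia markers (0.84), 3 of 10 for endothelial and mural cell markers (0.37), 4 of 5 for choroid plexus markers (0.37) and 3 of 6 for thalamus and habenula markers (0.58). Positive slopes were found in 5 of 12 neurogenesis and immature neuron genes (adjusted p = 0.54), 6 of 25 ribosomal protein genes (0.37), 24 of 65 oxidative phosphorylation genes (0.4) and 14 of 32 proteasome genes (0.67). GABA receptors and blood cell genes had fewer than 5 tested members and no list test. Adjusted over the list alone, 1 gene passed in all of these lists: Tcf7l2, a Wnt pathway transcription factor of the thalamus list, at 412, 622.5, 291 and 127.5 (slope −0.39 ± 0.1, SE, n = 4, adjusted p = 0.0161). Over all genes its adjusted p was 0.99993, and a second Tcf7l2 probe set, with a mean under the filter, read 82, 83, 117.5 and 109. Without the 1 h sample the lists called by camera were glutamate receptors and presynaptic vesicle genes, and without the 2 h sample choroid plexus markers were called beside the clock genes. Without the 6 h sample choroid plexus markers were the 1 list called. These calls were made at the preset correlation. With an estimated one, 0 lists were called without any 1 of the 4 samples, with 1 residual degree of freedom. Even with all 4 samples, that setting called a planted list in 0% of simulations at a slope of 0.1 and 15% at 0.4. The missed calls alone therefore cannot tell whether the calls depend on the preset correlation. The estimates with all 4 samples were 0.54 for choroid plexus markers, 0.27 for presynaptic vesicle genes and 0.08 for glutamate receptors. All lie above the preset of 0.01. At such values the preset understates the shared scatter of these lists, so these calls carry little weight.

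Single arrays differed by more than 2-fold at named genes in each hour, with no replicate against which to test it. Transthyretin (Ttr), the thyroid hormone carrier made by choroid plexus epithelium, stood furthest out: it read 81.3, 234, 2408 and 191, 15.7-fold above the mean of the other 3 hours at 4 h. The probes of Laptm4a, a lysosomal membrane protein, and Dynll2, a dynein light chain, stood 4.49-fold and 4.8-fold above the other hours at 2 h. Thyrotropin-releasing hormone (Trh) was lowest at 1 h, with 30.7, 273, 407 and 272, at least 8.13-fold under the other hours. Over all genes past the filter, 741 of 4951 (15%) spanned over 2-fold between their highest and lowest hour and 92 spanned over 4-fold.

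At 1 h, the neurotrophin-3 receptor gene Ntrk3 (783, 223, 264 and 344.5), the secreted Wnt antagonist Frzb (477, 185, 217 and 191) and the laminin gene Lamc1 (469, 117, 123 and 218.5) were above all other hours, and the lipopolysaccharide-binding protein gene Lbp (63.9, 391, 412 and 341) and Pdzk1ip1 (57.8, 415, 236.5 and 370.3) were below them. At 2 h, the heme-binding protein gene Hebp1 (258, 873, 122 and 385) was above, and the T cell kinase Zap70 (425, 60.8, 534.5 and 377), the histone acetyltransferase Kat2a (554, 95.9, 721 and 527) and the phosphatase Dusp2 (551, 80.9, 377 and 382) were below. At 4 h, Mug-ps1 (137, 131, 602 and 79.3) and the alcohol dehydrogenase Adh7 (251, 171.5, 1027 and 265) were above, and Slc35g3 (472, 436.5, 51.3 and 318), Prpsap1 (503, 409, 73.2 and 340.5) and the serotonin receptor Htr7 (269, 312, 59.4 and 360.1) were below. At 6 h, Dnajc11 (124.5, 144, 127 and 486), the potassium channel gene Kcnj9 (217, 186.5, 230.3 and 627) and Pcp2 (297, 224.5, 243 and 741) were above, while Ada, Nubp1 and Mrpl11 were below. Beside that of Ada above the floor at 6 h, second probe sets of Kcnj9, Lamc1 and Zap70 did not share the peak or dip: Kcnj9 read 158, 50.4, 138 and 73.2, and Lamc1 49.8, 94.1, 133 and 9.9, while 2 more Zap70 probe sets read 45.7, 82.4, 149 and 142 and 125, 225, 79 and 169. A second Pcp2 probe set read 186, 185, 179.7 and 223, and a second Dynll2 probe set, also highest at 2 h but over a narrower range, 1179, 1278, 999 and 957.

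Genes more than 2-fold below every other hour outnumbered those above at each hour. There were 33 below and 4 above at 1 h, 31 and 9 at 2 h, 48 and 18 at 4 h, and 32 and 6 at 6 h. The filter on the mean of the same arrays keeps genes with a single value near the floor among moderate ones. It tends to drop genes with a single moderate value among values near the floor. The excess of low values may therefore come from the filter, which was not tested. The 4 h array held the highest of the 4 values for 1556 genes and the lowest for 1448, against 1106 to 1145 and 1142 to 1213 at the other hours. Without the 4 h sample, 377 genes spanned over 2-fold, and without another sample 513 to 529 did. Scaling each array to its median would place the median of all genes at 4 h at −0.17 log2 against the other hours, where it is 0.02 as deposited. Between pairs of arrays, Pearson's r across 4951 genes ran from 0.929 (4 against 6 h) to 0.956 (1 against 6 h), and the SD of log2 differences from 0.43 to 0.54. The number of genes over 2-fold apart ran from 152 (1 against 6 h) to 295 (1 against 4 h).

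Many synaptic genes had their highest value at 1 h and their lowest at 2 h, including 10 of 17 presynaptic vesicle genes for the first and 9 for the second. The AMPA receptor subunit genes Gria1 (6708, 3195, 3779.7 and 6383), Gria2 (12833, 7718, 8992 and 10505) and Gria3 (479, 128, 187 and 329.8) and the delta receptor gene Grid1 (530.4, 210.3, 115 and 343) were highest at 1 h. Among presynaptic vesicle genes the same was seen for complexin 2 (Cplx2, 2703, 638, 1044 and 2128), the vesicle fusion ATPase Nsf (11894, 5771, 7196.5 and 9503), synaptotagmin 1 (Syt1, 1166, 566, 790.3 and 779), syntaxin 1A (Stx1a, 1233.5, 549.7, 898 and 857) and synaptophysin (Syp, 851, 500.3, 561 and 745). The small GTPase gene Rab3a was lowest at 4 h instead (394, 585, 164 and 646), the hour at which a second Rab3a probe set was highest (11.5, 8.5, 108 and 19.5). The NMDA receptor gene Grin2c (512, 827, 839.8 and 669) was lowest at 1 h.

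The median shift against the other 3 hours was 0.58 log2 at 1 h and −0.45 at 2 h for the 6 glutamate receptors, and 0.35 and −0.25 for the 17 presynaptic genes. All of these lay outside the central 95% of expression-matched random lists, at percentiles of 100, 0.09, 100 and 0.07, as did the glutamate receptors at 6 h (0.34, percentile 99.12). The 22 plasticity kinases and phosphatases shifted by 0.15 at 1 h (percentile 97.85), with the calcineurin subunit Ppp3cb at 1134, 562, 591 and 681 and the adenylyl cyclase Adcy8 at 186, 404, 271 and 236.5. That shift lay inside the central 95% with the filter at the 60th percentile (0.15, percentile 97.31) and with the mean of all probe sets (0.13, percentile 95.1), and was 0.23 without the 6 h sample. The granule cell markers stayed inside, at −0.06 at 1 h and 0.14 at 2 h, with Tiam1 at 973, 1679.9, 1039 and 1086 (58.7, 262, 385 and 214 in a second probe set) and Marcksl1 at 1875, 1715, 1745 and 1126. The ratio of 3' to 5' signal, a sign of RNA integrity, was 3.03, 2.48, 2.59 and 2.54 for Actb and 3.75, 6.33, 5.36 and 3.89 for Gapdh. With no filter on low genes the glutamate receptor shift was 0.02 at 1 h (percentile 57.71) and 0.17 at 6 h (percentile 91.41), both inside the central 95%. The presynaptic shift was then 0.2 at 1 h, still outside (percentile 99.37). With the filter at the 60th percentile the presynaptic shift was −0.4 at 2 h. At 6 h the glutamate receptor shift was 0.08 without the 2 h sample and 0.06 without the 4 h sample, both inside the central 95%, and 0.61 without the 1 h sample; with the mean of all probe sets it was 0.16, inside. At 2 h the glutamate receptor shift was −0.8 without the 4 h sample, and the presynaptic shift was −0.15 without the 1 h sample, both still outside.

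Choroid plexus and vascular markers differed between arrays in other ways. Beside Ttr, the choroid plexus genes Igfbp2 (395, 523, 746 and 294), Cab39l (342, 288, 577 and 379) and Lbp were highest at 4 h, while Igf2 was highest at 2 h (1849, 4402, 2955 and 2521). The median shift of the 5 genes was 0.92 at 4 h (percentile 99.97) and −0.79 at 1 h (percentile 0.01), where it was −0.4 over 7 genes with the mean of all probe sets (percentile 2.24). Endothelial and mural cell markers had a median shift of 0.46 at 2 h (percentile 99.96) and −0.38 at 6 h (percentile 0.35), with the glucose transporter gene Slc2a1 at 334, 357.5, 190.3 and 144, the tight junction gene Cldn5 at 705, 657.5, 516 and 379.8 and vitronectin (Vtn) at 390.2, 541.5, 216 and 458. The shift of the vascular list at 6 h was inside the central 95% with no filter (−0.22), with a floor at the 30th percentile (−0.19) or with the mean of all probe sets (−0.24).

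**Figure D2:**
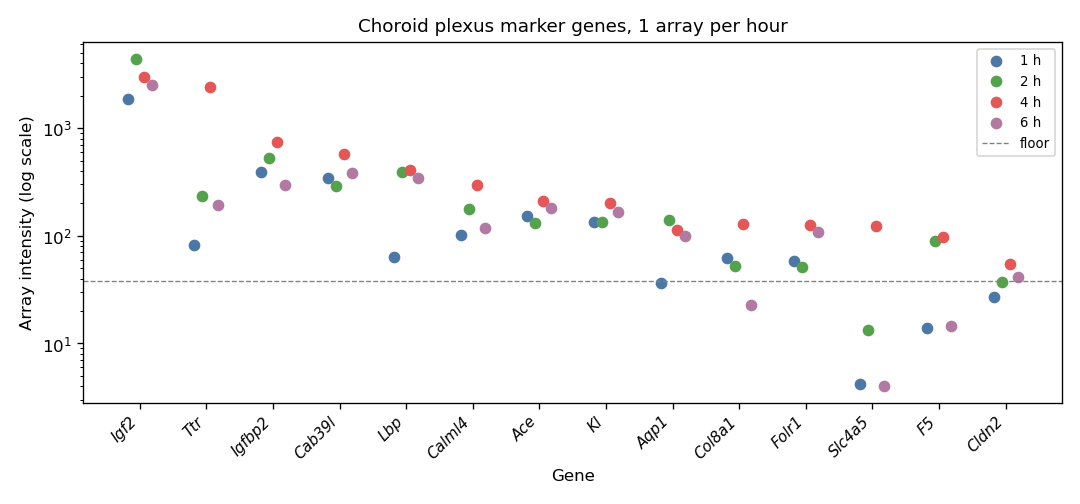
Array intensity (log scale) of the 14 choroid plexus marker genes with a probe, ordered by their highest value; each point is 1 array, coloured by hour, and the dashed line is the floor of 38.3. Ttr reads 2408 at 4 h and 81.3 to 234 at the other hours, and Igf2 is highest at 2 h.

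The medians of the clock and glucocorticoid response lists were also high at 6 h, with members in both directions. The median shift was 0.2 for the 14 clock genes (percentile 97.66) and 0.24 for the 19 glucocorticoid response genes (percentile 99.69), of which 10 were above all other hours and 5 below them (Angptl4, Cebpb, Fkbp5, Hif3a and Lcn2). Sgk1, a kinase induced by corticosteroids, was 1270.5 at 6 h and between 612 and 906 before. Per1, which belongs to both lists, was 564 at 6 h and between 299 and 358 before. The glucocorticoid list's shift was 0 with no filter and 0 with the mean of all probe sets, and inside the central 95% without the 1 h sample (0.17) or the 4 h sample (0.16). The clock list's shift was inside, at 0.18, with no filter, the filter at the 60th percentile, a floor at the 30th or an added constant, and without the 1 h (0.22) or the 2 h sample (0.13).

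Over 84 combinations of list and hour, 14 medians lay outside the central 95%, where independent draws of unrelated genes would give 4.2. Genes within a list are not unrelated. Their estimated correlation ran from −0.09 for microglia markers to 0.54 for choroid plexus markers. The shifts of a list at the 4 hours are also tied to each other. The excess over 4.2 is therefore not a measure against chance. The remaining 2 of the 14 medians were oligodendrocyte markers at 1 h (−0.18, percentile 1.53) and oxidative phosphorylation genes at 2 h (0.11, percentile 99.29). In the oligodendrocyte list, Gsn read 305, 642.5, 353 and 369 and the tight junction gene Cldn11 395.5, 539, 653 and 334. The oligodendrocyte shift was 0.06 when all probe sets of a gene were averaged, and inside without the 4 h sample (−0.11), with the filter at the 60th percentile (−0.05), with no filter (−0.16) and after quantile normalisation (−0.17), and the oxidative phosphorylation shift was 0.09, inside, without the 6 h sample. Lists inside at every hour included immediate early genes (−0.04 to 0.08), astrocyte markers (−0.07 to 0.14), microglia markers (−0.03 to 0.07), interneuron markers (−0.16 to 0.1) and proteasome genes (−0.08 to 0.04).

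**Figure D3:**
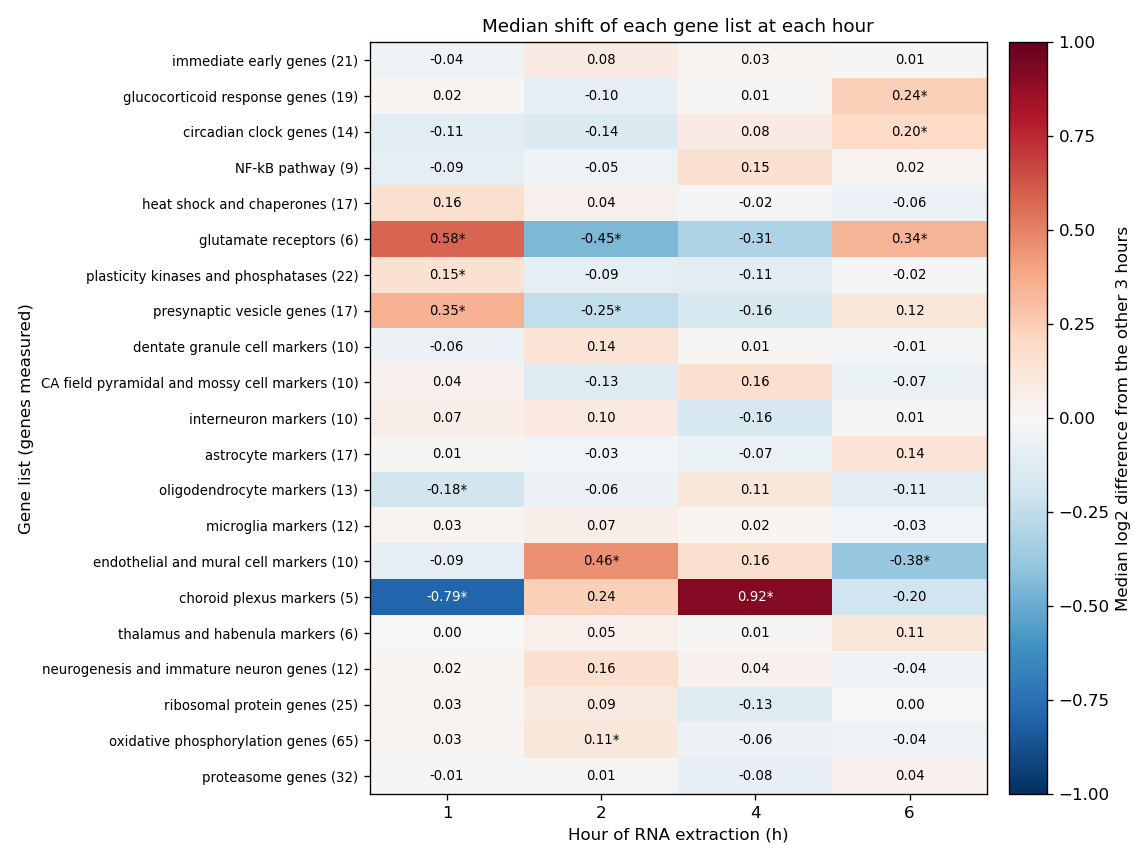
Median log2 difference of each gene list (vertical axis, number of measured genes in brackets) at each hour (horizontal axis) from the mean of the other 3 hours; colour and number give the shift, and an asterisk marks 14 medians outside the central 95% of expression-matched random lists. The outermost are choroid plexus markers, at 0.92 for 4 h and −0.79 for 1 h.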

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

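The gap rule used here, in which 1 of the 4 arrays lies far from the nearest of the others relative to the whole range, was fixed before the data were examined, and no test in this part was chosen after its result was seen. Of 109 values tested for named genes and arrays, 24 met it. Chance gives about 1 in 20, and over all genes past the filter 282 of 4951 (5.7%) met it. The named genes include those picked for standing apart at a single hour, which raises their share, and no explanation was tested for single genes.

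Genes far below the nearest other hour at 1 h, with their intensity there and the nearest other value, were Idnk (115 against 311), Trh (30.7 against 272), Lbp (63.9 against 341) and Atp5pb (99 against 270.5). At 2 h they were Zap70 (60.8 against 377), Kat2a (95.9 against 527) and Lhx6 (141 against 280). At 4 h they were Htr7 (59.4 against 269), Cdkn1a (83.7 against 273), Hspd1 (3054 against 5509) and Gja1 (4646 against 6577). At 6 h they were Nubp1 (52.7 against 303), Khdrbs1 (98.2 against 223), Atf6 (218 against 474.5), Ier2 (93.9 against 209.5) and Nes (79.4 against 265). Genes far above the nearest other hour were Frzb (477 against 217) at 1 h, Dynll2 (6106 against 1424), Calb1 (3026 against 2542) and Ncam1 (4558.5 against 3778) at 2 h and Dnajc11 (486 against 144) at 6 h. The Trh value lies under the floor of 38.3, which bounds its ratio from below. In the order 1, 2, 4 and 6 h, second probe sets read 171, 236, 185.5 and 178 for Cdkn1a, 1179, 1278, 999 and 957 for Dynll2, 284, 266.5, 236 and 346 for Hspd1, 544.5, 408.5, 478 and 467 for Ncam1, and 391, 245, 202.5 and 329.6 for Gja1. Of these, the Hspd1 and Gja1 probe sets were lowest at 4 h as well, and that of Ncam1 was lowest at 2 h. For Nes, a second probe set lay under the floor at every hour and shows no course.

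Whole arrays met the rule in 3 values. The median intensity of the 4 h array was 213, with 187 the nearest other. The 3' probe set of 18S ribosomal RNA read 1031 on the 1 h array against 2277 for the nearest other, and the middle probe set of 18S read 169 against 521.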

How the results depend on the processing

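The leave-one-out values for list shifts, list members and array agreement, the other alternatives for array agreement, the count of list members with no filter, and the estimated correlation with a sample left out were chosen after seeing the data. Trend genes stayed at 0 under every planned setting with all 4 samples, and left-out samples gave 0 to 13 (13 without 1 h, 3 without 6 h), where 1 residual degree of freedom remains and limma met genes with no variance. The clock list had adjusted p = 0.24 with a constant added in place of the floor, 0.073 for early against late hours, 0.84 with an estimated correlation, 0.13 with a filter at the 60th percentile, 0.21 with a floor at the 30th, 0.43 by fry and 0.22 with no filter. It ranged from 0.033 to 0.5 with a sample left out (0.08 without 1 h, 0.5 without 6 h). With an estimated correlation and a sample left out it was 0.89, 0.95, 0.93 and 0.9 in the order of the hours, and 0 lists were called. The first 7 settings gave 0 called lists, log2 of the hour gave 2 (clock genes and choroid plexus markers), and left-out samples gave 1 to 2. Genes over 2-fold apart numbered 211 with a filter at the 60th percentile and 2652 with no filter, where more or fewer dim genes enter, and 377 to 529 with a sample left out (377 without 4 h). The lowest correlation between arrays was 0.941 with the stricter filter and 0.929 to 0.949 with a sample left out (0.949 without 4 h). List medians outside the central 95% numbered 6 of 64 with the stricter filter, against 14 of 84 in the main setting. Of those 6, 4 were among the 14. With a sample left out, 10 to 13 of 63 medians lay outside.

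The shift of oligodendrocyte markers at 1 h turned to 0.06 with the mean of all probe sets. Of 147 alternative values of the 14 list shifts, 121 stayed outside on the same side, 25 moved inside with their sign or to 0, and 1 turned. For named genes, 1266 of 1365 alternative values stayed within a set margin and 99 moved further, 23 of them with the mean of all probe sets. The margin was the SE for a slope and the SD of the other hours for an hour difference. For ranges and means it was the SD of the 4 samples. Under other codings of the hour, a slope counted as unmoved if it kept its sign. List members past the filter numbered 278 to 485 over the settings, against 351. All 549 alternative slopes and hour differences of named genes kept their sign. Most of these genes were picked for moving 1 way at every step or for standing apart from all other hours. For them, leaving out a sample or recoding the hour cannot turn the sign. The agreement in sign was thus largely fixed by the rule for naming genes. Apart from the genes, lists and sample numbers noted, the cause of these changes was not tested. Signal over background sets a limit: the share of genes over 2-fold apart was 6.4% under the stricter filter, 15% under the one used and 32.1% under none.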

Other observations

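The tests of clock phase, corticosteroid response, RNA quality, granule cell content, choroid plexus tissue and array scale, and the count of array orders over all lists, were chosen after the patterns had been seen. The tests of other array orders for the clock list and of gene length were set out before their results were known, the first for 12 orders. It was counted over 12 and over 24 orders, with the real order smallest either way, and the 24 were kept after the result was seen, because uneven spacing makes an order differ from its reverse.

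Lists too small to test held some wide ranges. Of the GABA receptor genes, 3 of 9 with a probe were past the filter: Gabra2, the alpha 2 subunit, read 499.9, 169, 216 and 1072, Gabrb1 7051, 4800, 5116 and 6477 and Gabbr1 3266, 3168, 3890.3 and 3305. Gabra2 and Gabrb1 were lowest at 2 h, the hour at which Gria1, Gria2 and Gria3 were lowest too. Hemoglobin genes, a measure of blood left in the tissue, read 4208, 2328, 2552 and 3814 for Hba-a1 and 486, 374, 342 and 484 for Hbb-b2, so that Hba-a1 spanned 1.81-fold. Neither list has a test, and these genes were not called by limma.

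Members of other lists with a wide range are given as values. In the neurogenesis list, where 3 of 12 genes spanned over 2-fold and the median shift was −0.04 to 0.16, inside the central 95% at every hour, cyclin D2 (Ccnd2) read 583, 103, 517 and 393 and nestin (Nes) 265, 323, 335 and 79.4. Their ranges of 2.5 and 2.08 log2 were 0.57 without the 2 h sample for Ccnd2 and 0.34 without the 6 h sample for Nes, and Tubb3 and Ncam1 ranged over 0.32 each. The interneuron transcription factors Dlx1 and Lhx6 read 130.1, 319, 93.8 and 243 and 289, 141, 280 and 289.9. Ccn3 of the CA field list read 425, 952.5, 663 and 1269 and the dopamine receptor gene Drd2 143, 159, 341 and 169, and the Wnt pathway factor Lef1 456, 222, 911 and 501. The microglial genes Irf8 and Csf3r read 132, 189, 268 and 163 and 1127, 599, 1191 and 648, and the astrocyte genes Slc4a4 and Gja1 1006, 622, 816 and 825.5 and 6949, 6610.3, 4646 and 6577. Among members past the filter, the widest ranges in the ribosomal list were those of Rps13 (186, 449, 178 and 354) and Rps4l (606.5, 855, 669 and 505). In the oxidative phosphorylation list they were those of Atp5pb (99, 310.1, 303 and 270.5) and Cox4i1 (473, 776, 281 and 557). In the proteasome list they were those of Psmd7 (925.5, 1538, 1285 and 827) and Psmd9 (412.5, 444.5, 701 and 604.5). A second Cox4i1 probe set read 229.7, 243, 217 and 179.7. Those of Nes (24.5, 22.9, 28.3 and 38.1) and Lef1 (20.1, 12.2, 22.9 and 31.7) lay under the floor of 38.3 at every hour. With the mean of all probe sets the range was 1.04 log2 for Nes and 1.02 for Lef1. None of these genes passed the limma trend test over all genes.

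The upward slope of clock genes over the hours may be a movement of clock phase with the time of day, as a hypothesis. The 7 measured genes driven through E-box and D-box elements, such as Dbp and Nr1d2, had a mean slope of 0.1 log2 per h against −0.01 for 3 genes under ROR and REV-ERB control, a difference of 0.12 (95% bootstrap interval over genes 0.06 to 0.18, two-sided exact permutation p = 0.058). Chance is not excluded: in 1 of the 24 orders of the unevenly spaced hours, the real one, the clock list had a camera p as small (permutation share 0.042, p = 0.00097 against 0.0012 for the nearest other), but the clock list was picked as the smallest of 21, and in 12 of the 24 orders some list had a p as small (down to 7.1e-08), while 15 orders called at least 1 list. A corticosteroid response to handling is open too, since 18 glucocorticoid response genes outside the clock list had a median slope of 0.008 and a camera p of 0.55, and the interval of the difference in median slope from the clock list, −0.028 to 0.133, includes 0. Clock phase and a corticosteroid response cannot be told apart with 1 array per hour.

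The high values of synaptic genes at 1 h and low values at 2 h may come from the tissue or from the RNA. Genomic length is argued against as the source. Over all genes its Spearman correlation with the shift was 0.07 at 1 h and −0.06 at 2 h. Transcript length and the place of a probe set in the transcript were not examined, so a bias through these stays open. Among random lists matched on expression and genomic length, the presynaptic list at 1 h lay at percentile 100 and at 2 h at 0.15. The glutamate receptors past the filter lay at 99.98 and 0.33. With no filter on low genes, and matching on expression alone, the glutamate receptor shift at 1 h was 0.02, inside the central 95%. A smaller share of granule cells in the 2 h array stays open, since their markers went both ways. The dim markers under the filter were all lower at 2 h than at 1 h. At 1 and 2 h they read 111.7 and 37 (Pcp4), 156.9 and 69.4 (Sema5a), 90.6 and 41.3 (Trpc6) and 212.5 and 191.4 (Rasgrp1). The markers past the filter argue against a smaller share. Their median change from 1 to 2 h was 0.18 log2 (95% bootstrap interval −0.13 to 0.52), against −0.24 (−0.92 to −0.19) for presynaptic genes. Among them, Prox1 fell from 184.2 to 153.5. These intervals run over genes within 1 pair of arrays and do not measure the spread between samples. Other neurons are not covered. Interneuron markers changed by −0.06 (−0.42 to 0.48), and CA field markers stood at −0.13 at 2 h (percentile 8.9), inside the central 95%. Vessels and RNA quality stay open. Vascular markers stood 0.46 above the other hours at 2 h (percentile 99.96) and changed by 0.28 from 1 to 2 h (interval −0.12 to 0.78). From 1 to 2 h the 3' to 5' ratio changed by a factor of 0.82 for Actb and 1.69 for Gapdh, in opposite directions. Over the 4 arrays the Gapdh ratio (3.75, 6.33, 5.36 and 3.89) ran in reverse order to the synaptic shifts. Those were 0.58, −0.45, −0.31 and 0.34 for glutamate receptors and 0.35, −0.25, −0.16 and 0.12 for presynaptic genes. The Actb ratio (3.03, 2.48, 2.59 and 2.54) was highest at 1 h, as these shifts were. The 18S probe sets of the 1 h array read 1031 and 169 against 2277 and 521 for the nearest other. A difference between hours or between animals is open and untested, since hour and array are the same here.

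The high Ttr at 4 h may come from choroid plexus tissue in that sample, a hypothesis formed on the same data that stays open, and no member of that list stands in another list. After quantile normalisation, 8 of the 13 other choroid plexus genes with a probe were highest at 4 h, where expression-matched random lists had a median of 4 (percentile 99.27), and with the deposited values 11 were, against 5 (percentile 99.98). But 9 of the 13 lie under the filter, 5 of them with a value at the floor, and of the 4 past it 2 were highest at 4 h after quantile normalisation (percentile 77.4) and 3 as deposited (percentile 93.81). The scale of the 4 h array is argued against as the source by its size. Scaling to the array median would place the median of all genes at 4 h at −0.17 log2 against the other hours. Ttr there stood 3.37 log2 above the highest other hour as deposited. Quantile normalisation left this gap at 3.37 and, at these sizes, could hardly have closed it. Not every abundant marker followed: Igf2, also made by the meninges, was 4402 at 2 h and 2955 at 4 h, and Igf2, Igfbp2 and Cab39l were above the filter of 170.4 at all 4 hours; whether Ttr differed with the hour itself is untested.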
